A study of Homo sapiens with 33 samples.

How the data were processed

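Bulk RNA sequencing of 33 human tumour samples gave 1 table of gene values per sample. Per the labels, total RNA was extracted with an RNeasy kit and libraries were made with a TruSeq kit. The submitters' processing notes name STAR, RSEM and Cufflinks and the build GRCh38, without versions or the role of each tool. The annotation release and the strand setting are not given in the sources used here. Per the file headers, the tables hold RSEM expected counts per gene, which the authors did not normalise. The authors also gave TPM, a length-scaled abundance, per the file headers, and every sample's values sum to nearly the same total. FPKM values, also scaled to gene length by the authors, are in the same tables per the file headers and were not used here.

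Expected counts were rounded to whole numbers, since 7.4% of the values were not whole at a tolerance of 1e-06. Of 61906 gene entries, 46 pseudoautosomal Y entries were added to their X entries, leaving 61860. Symbols were found for 61757 of these, and 58308 matched GENCODE release 29, from which positions and gene types were taken. 511 Y-linked and X inactivation entries were left out. Library totals ran from 4153632 to 88111968 counts. Protein-coding genes took a median of 95.1% of counts, mitochondrial genes 0.0517% and ribosomal protein genes 1.5%. Libraries were compared in pairs for duplicates by chi-square over 9957 genes.

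Counts were scaled by TMM (factors 0.661 to 1.17) and filtered with edgeR's filterByExpr without a group (minimum count 10, minimum total 15), which kept 15280 genes. Levels are TMM log2 CPM with a prior count of 2. A score is the mean z of these levels over a list, scaled to an SD of 1. Genes were tested against each of 3 covariates, the G2/M score, the CCND1 level and the basal-minus-classical score, with edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest) in R 4.3.3. Genes that build a score were left out of its counts. The same test compared the 3 title code sets of 20, 8 and 5 tumours. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. DESeq2 1.42.0 served as another test. On simulated data with 100 changed genes of each size, slopes of 1 were found for 94% of genes with the G2/M score, 95% with CCND1 and 96% with the basal-minus-classical score. Slopes of 0.5 were found for 61%, 55% and 60%. False calls were 5 of 160, 9 of 159 and 7 of 163. Genes were simulated independently, which real genes are not, so these do not measure the false calls of the real fits.

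Before the data were examined, 37 gene lists with 567 genes were fixed, of which 553 genes matched. The tests, the title code sets, the 26 pairs and most alternatives were fixed at the same time. Lists were tested with camera in limma 3.58.1, with the correlation between genes preset at 0.01 and again estimated, adjusted over the lists of a fit. Which lists the text describes was chosen after their results were seen. Genes were named by a rule fixed before the data were examined: 21 cell cycle, repair and subtype genes always, the 8 steepest rises and 8 steepest falls among protein-coding genes past the threshold with a mean log2 CPM of at least 1, up to 4 members with the smallest adjusted p of each list described, and the 15 protein-coding genes of mean log2 CPM of at least 5 with the largest SD. Some genes that this rule names, and some results that rest on them, are not reported. Correlations used two-sided permutation tests with 100000 resamples, then left out the 2 tumours farthest from the median of the x measure. The share of counts in a sample was given a Wilson interval from R's prop.test.

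Alternatives fixed before the data were examined were DESeq2 size factors, no count filter, a stricter filter of 1 CPM in 17 tumours, DESeq2's tests, epithelial and fibroblast scores or the title code set as covariates, leaving out the 2 farthest tumours, scores from log2 TPM, lists limited to expressed genes, and levels scaled by the library total alone. Alternatives chosen after seeing the data were the acinar score or the log2 library total as a covariate, leaving out the shallowest library alone or with the library of lowest epithelial score, and thinning to the shallowest total. For each fit, 40 orderings of the tumours, the real one included, were run. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.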

Results

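RNA from 33 human tumour samples was sequenced in bulk, with 1 library per sample. The series concerns the cell cycle and oxaliplatin resistance in pancreatic cancer, and oxaliplatin is a platinum drug that damages DNA. The labels put all 33 samples in 1 group, so relations across the tumours were measured and no groups were compared. The labels do not say that the samples came from separate donors, and p-values therefore measure the spread between these samples, which may be technical in part. The total expected count per library had a median of 15637054 and ran from 4153632 in tumour 2 to 88111968 in tumour 5. Between 16261 and 25704 genes had a count in a library. No 2 libraries agreed within sampling noise. Over 528 pairs and 9957 genes the lowest chi-square per degree of freedom was 40.8 and the highest correlation was 0.962. Slopes below are log2 changes per 1 SD of the stated score with their SE (n = 33), and their adjusted p-values come from edgeR's quasi-likelihood test over 15280 genes.

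The tumours differed most in the enzymes that pancreatic acinar cells secrete for digestion. Among protein-coding genes of high mean level, the 15 with the largest spread were all acinar products, led by the amylase AMY2A (SD 6.46 in log2 CPM, n = 33), the elastase CELA2A (SD 6.13) and the lipase PNLIP (SD 6.11). CELA3B, CPA1, CELA3A, CPB1, CTRC, CTRB1, PRSS1, CEL, CTRB2, GP2 and PRSS2 were among the others. The median SD over all tested genes was 0.71. The 22 acinar genes took a median of 0.224% of counts, from 0.00579% in tumour 14 to 34.9% in tumour 31. Their Wilson 95% intervals, which cover counting error only, were 0.00536% to 0.00624% and 34.91% to 34.96%. Amylases, elastases, chymotrypsinogens and trypsinogens come in families of near-identical genes, so how reads divide within a family is uncertain.

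Other tissue genes also varied. Fibroblast genes took a median of 1.95% of counts and their list mean had an SD of 0.87 in log2 CPM. The SD was 1.26 for smooth muscle genes, 1.81 for islet genes, 1.63 for adipocyte genes and 2.80 for enterocyte genes. Epithelial genes had an SD of 0.85. Their lowest score was in tumour 5, the deepest library, where the duct keratin KRT19 stood at 2.26 log2 CPM against a median of 7.69. Genes of nucleotide excision repair, which removes platinum adducts, had a more even list mean, with an SD of 0.16 and a span of 1.62-fold. G1 regulators spanned 2.07-fold. Averaging evens out genes that vary apart from each other. The median SD of single genes was 0.43 for nucleotide excision repair, 0.46 for G1 regulators and 1.47 for G2/M genes. E2F targets, which serve DNA replication, spanned 6.77-fold, and G2/M genes, which act in mitosis, 33.9-fold. Tumour 2 was lowest in both, and without it the spans were 3.77-fold and 16.5-fold.

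**Figure D1:**
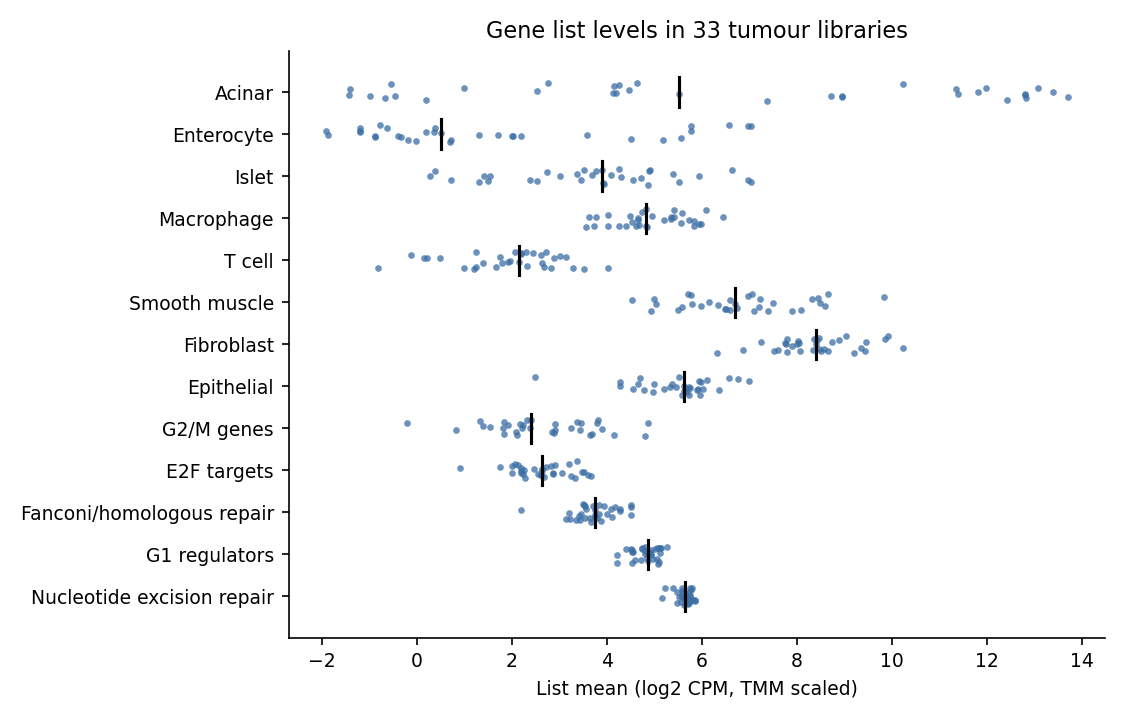
Mean level of 13 gene lists (log2 CPM) in 33 tumour libraries, with each dot a library and each bar the median over libraries. Acinar genes spread over 15.14 log2 units and nucleotide excision repair genes over 0.70.

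The D-type cyclins and the kinases they activate were expressed in all 33 tumours. CCND1, the cyclin D1 gene (ENSG00000110092.4, GRCh38 chromosome 11, 69641087 to 69654474), had a level of 6.28 ± 0.83 log2 CPM (mean ± SD, n = 33) and a range of 3.37 log2 units. CCND2 stood at 5.37 ± 0.80 and CCND3 at 5.51 ± 0.62 log2 CPM. The kinases varied less, with CDK4 (ENSG00000135446.17, chromosome 12, 57747727 to 57756013) at 4.98 ± 0.44 and CDK6 (ENSG00000105810.10, chromosome 7, 92604921 to 92836594) at 5.21 ± 0.48. CDK2 stood at 3.83 ± 0.33, and RB1, whose retinoblastoma protein restrains entry into S phase, at 6.99 ± 0.41. Cyclin E1, CCNE1, varied much more, at 0.51 ± 2.19, with no count in 5 tumours. The inhibitor genes CDKN2A (chromosome 9, 21967753 to 21995301) and CDKN2B (chromosome 9, 22002903 to 22009363) had no count in 3 and 1 of the tumours. Both overlap other genes, and whether strand was used to assign reads is not given in the sources used here. ATR, the replication stress kinase, stood at 7.49 ± 0.30, the excision repair gene ERCC1 at 5.89 ± 0.38, and the copper and platinum importer SLC31A1 at 2.25 ± 1.19.

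The relation to mitotic activity was measured with a score of 30 G2/M genes. Tumours with a higher score had higher levels of replication and mitosis genes outside the score, and lower levels of 4 of 12 acinar, 5 of 16 islet and all 4 tested adipocyte genes. At an adjusted p under 0.05, 922 genes were higher and 869 lower with the score. MELK, a mitotic kinase gene, rose by 1.44 ± 0.11 (adjusted p = 2.5e-11). The spindle gene CKAP2L rose by 1.43 ± 0.16, CEP55, which acts in the separation of daughter cells, by 1.42 ± 0.15, and the proliferation antigen MKI67 by 0.98 ± 0.11 (adjusted p = 6.5e-08). The largest slope belonged to the RNA-binding protein gene IGF2BP3, at 1.60 ± 0.26 (adjusted p = 9.21e-05). KLHDC7B at 1.49 ± 0.44, the calcium-binding S100P at 1.47 ± 0.27, the macrophage elastase MMP12 at 1.41 ± 0.26 and the B cell gene MS4A1 at 1.38 ± 0.44 were the other genes among the 8 steepest rises. With the acinar score as a covariate, 376 genes were higher and 390 lower. The KLHDC7B (slope 0.37, adjusted p = 0.713) and MMP12 (slope 0.96, adjusted p = 0.0531) calls were among those that ended. Without the 2 tumours farthest from the median score the counts were 487 and 364, and without tumour 2, the shallowest library, the MS4A1 call ended (slope 1.15, adjusted p = 0.0618).

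E2F targets rose with the score. Of 28 tested members 16 were higher and none lower (19 higher and 1 lower when adjusted over the list alone). The list ranked above other genes (camera adjusted p = 4.49e-14, and adjusted p = 3.25e-05 with an estimated correlation). It was the only list whose call in this fit held with an estimated correlation. The helicase subunit MCM4 rose by 0.59 ± 0.08, the ribonucleotide reductase subunit RRM2 by 0.87 ± 0.12, E2F8 by 1.07 ± 0.18 and DTL by 0.84 ± 0.14. E2F1 rose by 0.70 ± 0.18 (adjusted p = 0.01), a call that ended with the acinar covariate (slope 0.75, adjusted p = 0.0559). Replication histone genes, whose near-identical copies leave the division of reads uncertain, were higher for 8 of 14 (9 higher and 0 lower when adjusted over the list alone). Among them were H1-5 at 1.16 ± 0.18, H3C3 at 0.97 ± 0.22, H2AC13 at 1.11 ± 0.27 and H2AC11 at 0.79 ± 0.15 (camera adjusted p = 2.21e-07, and adjusted p = 0.201 with an estimated correlation). With the acinar covariate 3 histone genes were higher.

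Few G1 regulators passed. Of 15 tested members 2 were higher and 1 lower (2 higher and 1 lower when adjusted over the list alone). The list did not rank apart from other genes (camera adjusted p = 0.256). CCNE1 rose by 1.36 ± 0.29 (adjusted p = 0.00188) and E2F3 by 0.32 ± 0.10, while CCND2 had a slope of -0.41 ± 0.11 (adjusted p = 0.0129). CCND1 had a slope of 0.15 ± 0.14 (adjusted p = 0.508), CDK4 of 0.05 ± 0.08 (0.761), CDK6 of 0.15 ± 0.08 (0.22), none past the threshold. CCND3 had a slope of 0.20 ± 0.11, CDK2 of 0.05 ± 0.07 and RB1 of 0.14 ± 0.07, also short of it. Of 7 CDK inhibitor genes 1 was lower (0 higher and 1 lower when adjusted over the list alone), CDKN1A, the p21 gene, at -0.31 ± 0.10 (adjusted p = 0.0414). That list's median slope of 0.14 and its test, which pointed down, differed in sign (camera adjusted p = 0.975). CDKN1B, CDKN2A, CDKN2B and the neighbouring MTAP had slopes of 0.21 ± 0.14, 0.48 ± 0.38, 0.14 ± 0.27 and 0.05 ± 0.17. The E2F3 call ended with the acinar covariate (slope 0.24, adjusted p = 0.194) and without the 2 farthest tumours (slope 0.26, adjusted p = 0.115). Without tumour 2 the CCND2 (slope -0.33, adjusted p = 0.0592) and CDKN1A (slope -0.29, adjusted p = 0.0536) calls ended.

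Fanconi anaemia and homologous recombination genes, which repair crosslinks and breaks, were higher for 10 of 21 with none lower (10 higher and 1 lower when adjusted over the list alone). FANCI rose by 0.66 ± 0.07, EXO1 by 0.84 ± 0.15, BLM by 0.80 ± 0.16 and BRIP1 by 0.71 ± 0.14 (camera adjusted p = 9.17e-07, and adjusted p = 0.0593 with an estimated correlation). In the ATR and CHK1 checkpoint list 3 of 15 were higher (5 higher and 0 lower when adjusted over the list alone). CHEK1 rose by 0.86 ± 0.17, CLSPN by 0.50 ± 0.13 and WEE1 by 0.29 ± 0.08, while ATR had a slope of 0.04 ± 0.06 and TIMELESS of 0.21 ± 0.08 (camera adjusted p = 0.00862, and adjusted p = 0.18 with an estimated correlation). None of 14 nucleotide excision repair genes passed, over all genes or adjusted over the list alone, and their median slope was -0.01 (camera adjusted p = 0.454), with ERCC1 at 0.08 ± 0.07. Without tumour 2, DDB2 of that list (slope -0.23, adjusted p = 0.0388) and TIMELESS (slope 0.24, adjusted p = 0.037) were called. Targets of p53 were lower for 3 of 21 (0 higher and 4 lower when adjusted over the list alone), BTG2 at -0.61 ± 0.16, SESN1 at -0.33 ± 0.10 and CDKN1A (camera adjusted p = 0.0156, and adjusted p = 0.315 with an estimated correlation). Of 15 platinum transport and detoxification genes 1 was lower (2 higher and 3 lower when adjusted over the list alone), the metallothionein MT1X at -0.98 ± 0.24. That call ended without the 2 farthest tumours (slope -0.75, adjusted p = 0.0536) and with the acinar covariate (slope -0.52, adjusted p = 0.133), while the efflux pump ABCB1, at -0.33 ± 0.13, was called lower in 4 alternatives. SLC31A1 had a slope of -0.39 ± 0.15 (adjusted p = 0.0856), and was called lower with epithelial and fibroblast covariates (slope -0.53, adjusted p = 0.0203). SLC31A1 was highest in tumour 2, at 5.68 log2 CPM, against 3.76 in tumour 19, the next highest. Tumour 2 also had the lowest G2/M score, so this 1 library weighs heavily on the SLC31A1 slope. The platinum list's median slope was 0.04, its mean -0.06, and its test pointed down (camera adjusted p = 0.454). The WEE1 call was among those that ended with the acinar covariate (slope 0.15, adjusted p = 0.4), which kept 26 of the 59 calls followed in this fit. With that covariate 6 Fanconi and recombination genes were higher. Without the 2 farthest tumours 0 p53 targets and 1 checkpoint gene were called.

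Some acinar and islet genes and the tested adipocyte genes were lower with the G2/M score. The 8 steepest falls among single genes were CTRB2 at -2.33 ± 0.79, GP2 at -2.24 ± 0.75, CUZD1 at -2.16 ± 0.68, CTRL at -2.16 ± 0.62, ERP27 at -2.15 ± 0.64, AMY2B at -2.06 ± 0.55, GNMT at -1.94 ± 0.46 and PRSS3 at -1.87 ± 0.52. CTRB2, CTRL and PRSS3 encode digestive proteases and AMY2B an amylase. Of 12 tested acinar genes 4 were lower (0 higher and 12 lower when adjusted over the list alone). The list ranked below other genes (camera adjusted p = 5.77e-08, and adjusted p = 0.38 with an estimated correlation). Islet genes were lower for 5 of 16 (0 higher and 13 lower when adjusted over the list alone). The prohormone convertase gene PCSK1 had a slope of -0.86 ± 0.20, PAX6 of -0.70 ± 0.21, INSM1 of -0.81 ± 0.25 and SCGN of -1.12 ± 0.36 (camera adjusted p = 6.79e-07, and adjusted p = 0.381 with an estimated correlation). All 4 tested adipocyte genes were lower (0 higher and 4 lower when adjusted over the list alone). These were the lipid droplet genes PLIN4 at -0.91 ± 0.17 and PLIN1 at -1.22 ± 0.36, the lipase LPL at -0.72 ± 0.24 and FABP4 at -1.18 ± 0.40 (camera adjusted p = 0.0096, and adjusted p = 0.381 with an estimated correlation). With the acinar covariate 0 acinar, 1 islet and 3 adipocyte genes were lower, and CUZD1, ERP27, GNMT and PRSS3 had slopes above 0. With epithelial and fibroblast covariates the counts were 3, 0 and 1, and the PLIN1 (slope -0.32, adjusted p = 0.664), FABP4 (slope -0.41, adjusted p = 0.667) and LPL (slope -0.23, adjusted p = 0.566) calls ended. Without the 2 farthest tumours these counts were 0, 1 and 1, and without tumour 2 alone 7 acinar and 8 islet genes were lower.

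Smaller groups of genes moved in other compartments. Interferon response genes were higher for 5 of 16 (7 higher and 0 lower when adjusted over the list alone). They included MX2 at 0.59 ± 0.12, RSAD2 at 0.80 ± 0.22 and MX1 at 0.60 ± 0.18 (camera adjusted p = 0.000115, and adjusted p = 0.489 with an estimated correlation). Basal subtype genes were higher for 4 of 7 (6 higher and 0 lower when adjusted over the list alone). These were the keratins KRT17 at 1.21 ± 0.38 and KRT7 at 0.86 ± 0.25, the glucose transporter SLC2A1 at 0.72 ± 0.21 and AREG at 0.53 ± 0.15 (camera adjusted p = 0.00193, and adjusted p = 0.379 with an estimated correlation). Of 19 epithelial genes 2 were higher, among them KRT19 at 0.67 ± 0.22 (3 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00562, and adjusted p = 0.566 with an estimated correlation). No fibroblast, T cell or smooth muscle gene passed, over all genes or adjusted over the list alone. With the title code set as a covariate the fibroblast genes CTHRC1 (slope 0.41, adjusted p = 0.0406), FN1 (slope 0.43, adjusted p = 0.0492) and POSTN (slope 0.53, adjusted p = 0.0474) were called, and without tumour 2 CTHRC1 (slope 0.50, adjusted p = 0.0292) and POSTN (slope 0.68, adjusted p = 0.0377). The T cell gene CD2 was called without the 2 farthest tumours (slope 0.51, adjusted p = 0.0376), and DESeq2 called LCK (slope 0.50, adjusted p = 0.0427) and the smooth muscle genes LMOD1 (slope -0.53, adjusted p = 0.0385) and MYH11 (slope -0.75, adjusted p = 0.0454). The median slope was 0.17 for 20 fibroblast genes (camera adjusted p = 0.104) and 0.32 for 12 T cell genes (camera adjusted p = 0.066). For 11 smooth muscle genes it was -0.45 (camera adjusted p = 0.0332, and adjusted p = 0.584 with an estimated correlation). MS4A1 was the 1 call among 7 B and plasma cell genes (2 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0572). DESeq2 also called BLK (slope 0.94, adjusted p = 0.00762), FCRL5 (slope 0.93, adjusted p = 0.0413) and POU2AF1 (slope 0.61, adjusted p = 0.0417), and BLK was called without the 2 farthest tumours (slope 1.05, adjusted p = 0.0307). With the acinar covariate 1 interferon and 0 basal genes were called, and with epithelial and fibroblast covariates 2 and 0, with KRT19 not called (slope 0.34, adjusted p = 0.117).

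**Figure D2:**
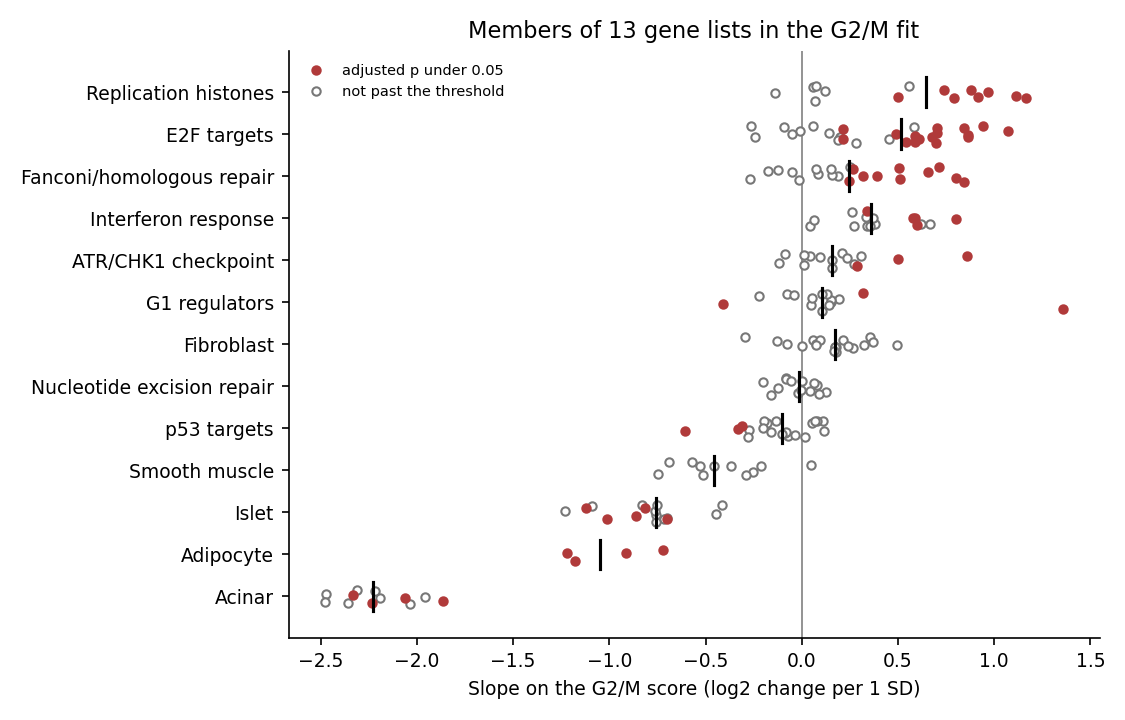
Slopes on the G2/M score (log2 change per 1 SD, n = 33) of the tested members of 13 gene lists, with genes at an adjusted p under 0.05 in red and list medians as black bars. Of the tested members 16 of 28 E2F targets rose, 4 of 12 acinar genes fell, and no nucleotide excision repair gene passed.

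Of 26 pairs of measures, tested by two-sided permutation with 100000 resamples and adjusted together, 8 passed. Sets A and B are title code sets of 20 and 8 tumours, and set C, with 5, was too small for a value. The E2F score rose with the G2/M score (r = 0.865, p = 1e-05, adjusted p = 0.00013, rho = 0.785 with p = 1e-05, r = 0.83 without the 2 farthest tumours, 0.855 in set A and 0.985 in set B). A p of 1e-05 is the smallest that the permutations can give. CCNE1 rose with it (r = 0.595, p = 0.00017, adjusted p = 0.0011, rho = 0.693 with p = 3e-05, r = 0.611 without the 2 farthest tumours, 0.669 in set A and 0.597 in set B). CCND1 showed no detectable relation (r = 0.119, p = 0.511, adjusted p = 0.554, rho = 0.0314 with p = 0.863, r = -0.0263 without the 2 farthest tumours, 0.046 in set A and 0.499 in set B). The 95% interval of its r ran from -0.234 to 0.444. CDK4 did not pass (r = 0.141, p = 0.436, adjusted p = 0.52, rho = 0.11 with p = 0.542, r = 0.272 without the 2 farthest tumours, 0.359 in set A and -0.271 in set B). CDK6 did not either (r = 0.291, p = 0.101, adjusted p = 0.149, rho = 0.294 with p = 0.0971, r = 0.0764 without the 2 farthest tumours, -0.0363 in set A and 0.798 in set B). Both passed on the log2 TPM scale (r = 0.463, adjusted p = 0.0138, and r = 0.41, adjusted p = 0.0311). CCND2 fell (r = -0.588, p = 0.00032, adjusted p = 0.00166, rho = -0.47 with p = 0.00627, r = -0.395 without the 2 farthest tumours, -0.363 in set A and -0.947 in set B). Its call ended without the 2 farthest tumours (r = -0.395, adjusted p = 0.0539) and on the log2 TPM scale (r = -0.283, adjusted p = 0.155).

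**Figure D3:**
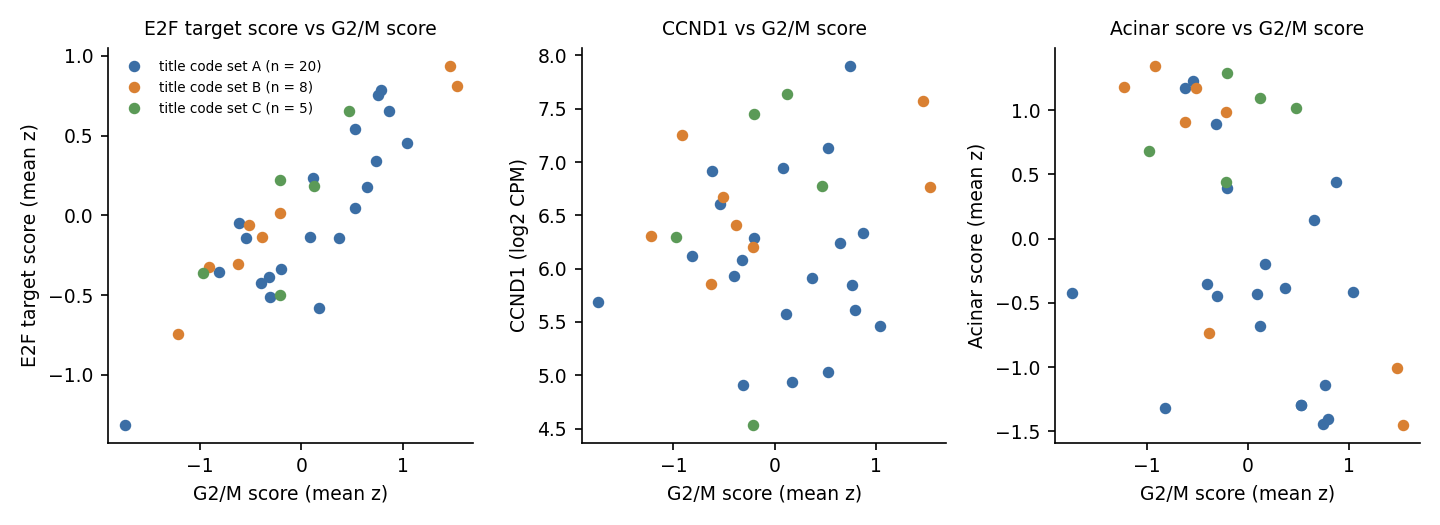
E2F target score (mean z), CCND1 level (log2 CPM) and acinar score (mean z) against the G2/M score, with each dot 1 of 33 tumours, coloured by title code set. The E2F score rose with the G2/M score (r = 0.865), CCND1 did not detectably follow it (r = 0.119), and the acinar score fell (r = -0.513).

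The Fanconi and recombination score rose with the G2/M score (r = 0.776, p = 1e-05, adjusted p = 0.00013, rho = 0.749 with p = 1e-05, r = 0.742 without the 2 farthest tumours, 0.788 in set A and 0.949 in set B). So did the checkpoint score (r = 0.663, p = 4e-05, adjusted p = 0.000347, rho = 0.601 with p = 0.00029, r = 0.615 without the 2 farthest tumours, 0.744 in set A and 0.659 in set B). The p53 target score fell (r = -0.503, p = 0.0027, adjusted p = 0.0104, rho = -0.306 with p = 0.0826, r = -0.421 without the 2 farthest tumours, -0.517 in set A and -0.721 in set B). CDKN1A fell as well (r = -0.451, p = 0.00799, adjusted p = 0.026, rho = -0.472 with p = 0.00607, r = -0.447 without the 2 farthest tumours, -0.314 in set A and -0.65 in set B). Nucleotide excision repair genes did not pass (r = -0.14, p = 0.44, adjusted p = 0.52, rho = -0.291 with p = 0.101, r = -0.173 without the 2 farthest tumours, -0.058 in set A and -0.448 in set B). T cell genes did not pass over all tumours (r = 0.356, p = 0.041, adjusted p = 0.082, rho = 0.308 with p = 0.08, r = 0.587 without the 2 farthest tumours, 0.596 in set A and -0.0381 in set B). Epithelial genes did not either (r = 0.365, p = 0.037, adjusted p = 0.0802, rho = 0.387 with p = 0.0274, r = 0.287 without the 2 farthest tumours, 0.263 in set A and 0.623 in set B). On the log2 TPM scale the p53 relation (r = 0.408, adjusted p = 0.0317) and the excision repair relation (r = 0.606, adjusted p = 0.000557) had the opposite sign. The 10 pairs not described here or below had adjusted p-values from 0.0653 to 0.761.

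The level of CCND1 was the next axis, since cyclin D1 drives the G1 phase of the cell cycle. Tumours with more CCND1 had higher levels of 954 genes and lower levels of 754, some MYC targets among the former. Among the steepest falls were MUC2, the intestinal gel-forming mucin, at -2.46 ± 0.65 (adjusted p = 0.0169), the lipoprotein gene APOB at -2.10 ± 0.62, FOLH1 at -1.71 ± 0.52, and MALRD1 at -1.63 ± 0.40. They also included the brush border myosin MYO1A at -1.38 ± 0.45 and PRAP1 at -1.33 ± 0.36. The steepest rises were KLK1 at 1.84 ± 0.60 (adjusted p = 0.0433), CTRL at 1.82 ± 0.52, the trypsin inhibitor SPINK1 at 1.65 ± 0.52, AMY2B at 1.61 ± 0.53, GNMT at 1.60 ± 0.52, GATM at 1.52 ± 0.44, GCAT at 1.41 ± 0.36 and TMEM97 at 1.32 ± 0.38. These 8 genes had slopes below 0, none past the threshold, when the CCND1 level was taken from TPM. Then 246 genes were higher and 109 lower, 206 of them among the 1708. With the title code set as a covariate 308 were higher and 358 lower.

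Cell cycle genes did not pass with CCND1, apart from a few. CDK4 had a slope of 0.16 ± 0.07 (adjusted p = 0.124), CDK6 of 0.16 ± 0.08 (0.193), RB1 of 0.17 ± 0.07 (0.0744), MKI67 of 0.04 ± 0.20 and E2F1 of 0.06 ± 0.18. None of 14 other G1 regulators (camera adjusted p = 0.567) and none of 27 G2/M genes (camera adjusted p = 0.444) was called, over all genes or adjusted over the list alone. With epithelial and fibroblast covariates RB1 (slope 0.20, adjusted p = 0.045) and ESPL1 (slope -0.52, adjusted p = 0.039) were. Of 28 E2F targets PCNA at 0.70 ± 0.17 and RRM1 at 0.29 ± 0.09 were higher (2 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0697). Per tumour, CDK4 did not pass against CCND1 (r = 0.389, p = 0.0251, adjusted p = 0.0653, rho = 0.411 with p = 0.018, r = 0.432 without the 2 farthest tumours, 0.455 in set A and -0.042 in set B). The same held for CDK6 (r = 0.348, p = 0.0468, adjusted p = 0.0836, rho = 0.37 with p = 0.0347, r = 0.344 without the 2 farthest tumours, 0.333 in set A and 0.211 in set B).

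MYC targets were higher for 4 of 16 (4 higher and 0 lower when adjusted over the list alone). These were nucleolin NCL at 0.42 ± 0.09, the chaperonin HSPD1 at 0.46 ± 0.11, the spermidine synthase SRM at 0.33 ± 0.09 and PA2G4 at 0.23 ± 0.07 (camera adjusted p = 0.00863, and adjusted p = 0.872 with an estimated correlation). Hypoxia genes were higher for 3 of 14 (4 higher and 0 lower when adjusted over the list alone). These were the collagen hydroxylase P4HA1 at 0.36 ± 0.10 and the glycolytic PGK1 at 0.44 ± 0.14 and ENO1 at 0.37 ± 0.12 (camera adjusted p = 0.0216, and adjusted p = 0.872 with an estimated correlation). All 3 calls ended with epithelial and fibroblast covariates (P4HA1 slope 0.28, adjusted p = 0.0619, PGK1 slope 0.23, adjusted p = 0.104, ENO1 slope 0.19, adjusted p = 0.0677), as did that of RRM1 (slope 0.26, adjusted p = 0.0676). Other alternatives ended more calls. Of the 41 followed in this fit, 13 were kept with the title code set as a covariate and 8 with CCND1 from log2 TPM. Of 19 epithelial genes SPINT2 at 0.61 ± 0.13 and the cadherin CDH1 at 0.50 ± 0.13 were higher (2 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0216, and adjusted p = 0.872 with an estimated correlation). Of 12 acinar genes AMY2B was higher (12 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0216, and adjusted p = 0.872 with an estimated correlation). Classical subtype genes were lower for 3 of 17 (0 higher and 3 lower when adjusted over the list alone), the intestinal genes CDH17 at -1.24 ± 0.35, BTNL8 at -1.25 ± 0.39 and MYO1A (camera adjusted p = 0.0419, and adjusted p = 0.872 with an estimated correlation). MUC2 was the 1 call among 3 tested genes of the enterocyte list (0 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.345). Of 11 smooth muscle genes SYNPO2 was lower at -0.84 ± 0.23 (0 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.0811).

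Genes of platinum handling and DNA repair went both ways with CCND1. Few calls followed in this fit held with the title code set as a covariate (13 of 41) or with CCND1 from log2 TPM (8 of 41). Of 15 platinum transport and detoxification genes 2 were higher and 2 lower (2 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.79). The copper and platinum exporter ATP7B had a slope of -0.70 ± 0.15 (adjusted p = 0.0054) and the drug transporter ABCC2 of -0.79 ± 0.21, while the metallothionein MT2A rose by 0.36 ± 0.11 and the glutathione transferase GSTP1 by 0.31 ± 0.10, a call that ended with epithelial and fibroblast covariates (slope 0.21, adjusted p = 0.0705). Nucleotide excision repair genes were higher for 3 of 14 and lower for 1 (3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.444). ERCC2 stood at 0.27 ± 0.07 and RAD23B at 0.26 ± 0.07, against ERCC5 at -0.19 ± 0.06, and ERCC1 at 0.06 ± 0.06 not called. Among 21 Fanconi and recombination genes RBBP8 rose by 0.39 ± 0.11, while XRCC3 at -0.50 ± 0.15 and SLX4 at -0.29 ± 0.10 were lower (1 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.232).

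Genes beside CCND1 on chromosome 11 did not follow it as a set. Of 9 tested neighbours CTTN, the cortactin gene, was higher at 0.28 ± 0.09 (adjusted p = 0.0363; 1 higher and 0 lower when adjusted over the list alone). LTO1 had a slope of -0.21 ± 0.08, MYEOV of -0.51 ± 0.29 and IGHMBP2 of -0.18 ± 0.10. With epithelial and fibroblast covariates MYEOV was called lower (slope -0.998, adjusted p = 0.00227). The median slope was 0.01 and the mean -0.03, with the test pointing down (camera adjusted p = 0.79). The CTTN call ended with the title code set as a covariate (slope 0.31, adjusted p = 0.0533), without the 2 farthest tumours (slope 0.26, adjusted p = 0.0515) and with epithelial and fibroblast covariates (slope 0.19, adjusted p = 0.071).

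**Figure D4:**
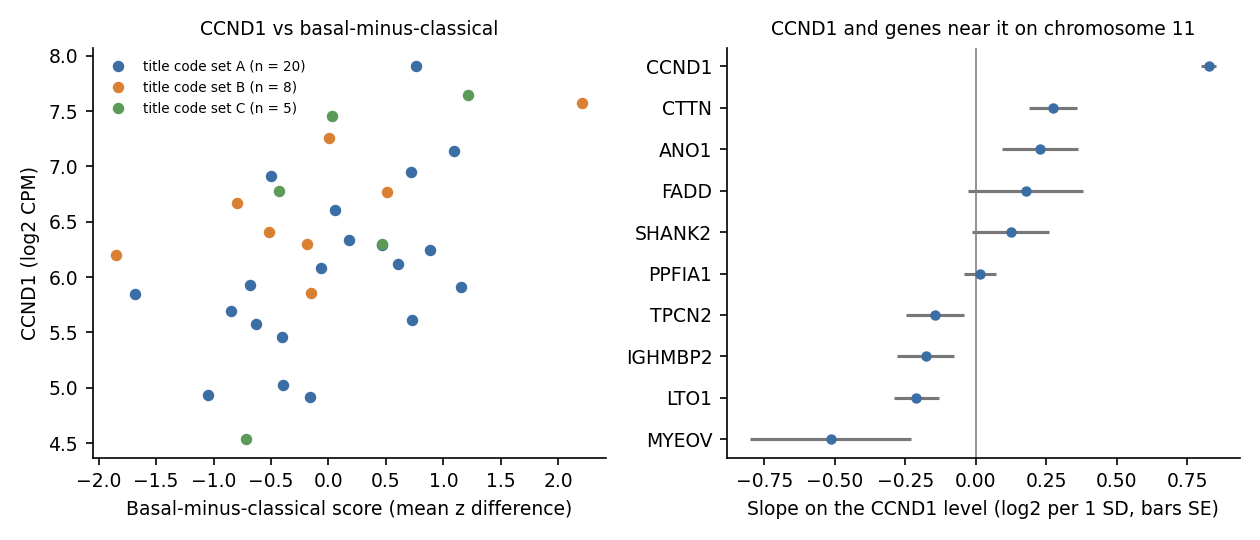
Left, CCND1 level (log2 CPM) against the basal-minus-classical score (difference of mean z) in 33 tumours coloured by title code set, and right, slopes on the CCND1 level (log2 per 1 SD, bars SE) of CCND1 and 9 neighbouring genes. CCND1 rose with the score (r = 0.503), and CTTN was the neighbour past the threshold.

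The basal-minus-classical score sets basal-like against classical markers, the best known expression axis of pancreatic tumours. It weighs all 23 basal genes alike, although only 7 of them passed the count filter and the list's median level was 0.08 log2 CPM. Its basal part therefore rests largely on genes of low level. Tumours toward the basal end had 203 genes at higher and 152 at lower levels, the tested genes of the enterocyte list among the latter. MUC2 had a slope of -2.59 ± 0.52 (adjusted p = 0.00441), APOB of -2.31 ± 0.47 and FOLH1 of -1.96 ± 0.41. The gluconeogenic PCK1 had a slope of -1.63 ± 0.40 and MS4A8 of -1.49 ± 0.30. ANXA8, which has near-identical copies and so an uncertain share of reads, rose by 1.54 ± 0.43, VSTM2L by 1.30 ± 0.26, the retinoic acid-binding CRABP2 by 1.01 ± 0.25, and TMEM158 by 0.97 ± 0.24. C5AR2 rose by 0.93 ± 0.22, CLIC3 by 0.91 ± 0.25, the caveolin CAV2 by 0.90 ± 0.13 (adjusted p = 0.000238) and the keratin KRT80 by 0.84 ± 0.21. Without the 2 farthest tumours 9 genes were higher and 54 lower, and CAV2 was not called (slope 0.44, adjusted p = 0.27). With epithelial and fibroblast covariates the CRABP2 (slope 0.66, adjusted p = 0.139), CLIC3 (slope 0.72, adjusted p = 0.0703) and KRT80 (slope 0.78, adjusted p = 0.0524) calls ended.

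The classical part of the score holds intestinal genes, among them CDH17 and MYO1A, so lower levels of other intestinal genes toward the basal end are in part built into it. All 3 tested genes of the 12 in the enterocyte list were lower (0 higher and 3 lower when adjusted over the list alone). They were the intestinal mucin MUC2, villin VIL1 at -0.90 ± 0.20 and the peptidase ANPEP at -1.10 ± 0.31 (camera adjusted p = 2.45e-06, and adjusted p = 0.00572 with an estimated correlation). This was the only list whose call in this fit held with an estimated correlation. Of 7 hepatocyte genes APOB and CPS1, at -1.07 ± 0.29, were lower (0 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.123). With epithelial and fibroblast covariates ANPEP (slope -0.98, adjusted p = 0.0885) and CPS1 (slope -1.01, adjusted p = 0.0592) were not called. Platinum transport genes were lower for 3 of 15 (0 higher and 3 lower when adjusted over the list alone). These were the transporters ABCC2 at -0.92 ± 0.17, ATP7B at -0.76 ± 0.15 and the efflux pump ABCB1 at -0.47 ± 0.12 (camera adjusted p = 0.057). P4HA1, at 0.46 ± 0.09, was the 1 call among 14 hypoxia genes (1 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0086, and adjusted p = 0.481 with an estimated correlation). MCM4, at 0.36 ± 0.09, was the 1 call among 28 E2F targets (1 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00929, and adjusted p = 0.729 with an estimated correlation).

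Further lists ranked apart from other genes on this axis without a member past the threshold. The 27 G2/M genes had a median slope of 0.31 (0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 1.44e-06, and adjusted p = 0.556 with an estimated correlation). For 15 checkpoint genes it was 0.09 (0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0269, and adjusted p = 0.421 with an estimated correlation). The median was 0.28 for 20 fibroblast genes (0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00676, and adjusted p = 0.784 with an estimated correlation). It was 0.23 for 14 macrophage genes (1 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0086, and adjusted p = 0.75 with an estimated correlation). It was 0.35 for 12 immediate early genes (0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0166, and adjusted p = 0.75 with an estimated correlation). Acinar genes, 12 in number, had a median of -0.57 (0 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.784 with an estimated correlation). DESeq2 called the macrophage gene CD14 (slope 0.52, adjusted p = 0.0227) and the immediate early genes EGR3 (slope 0.63, adjusted p = 0.0488) and FOSB (slope 0.68, adjusted p = 0.0447), and 1 fibroblast gene was called lower with epithelial and fibroblast covariates. GATA6, a classical subtype regulator, had a slope of -0.30 ± 0.11 (adjusted p = 0.17). CCND1 had a slope of 0.41 ± 0.12 (adjusted p = 0.051), past the threshold in 7 alternatives. Its correlation with the score passed (r = 0.503, p = 0.0028, adjusted p = 0.0104, rho = 0.493 with p = 0.00411, r = 0.479 without the 2 farthest tumours, 0.504 in set A and 0.699 in set B).

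Sample titles end in 1 of 3 codes whose meaning the labels do not give, and these sets of 20, 8 and 5 tumours were compared as a possible batch. No gene differed among them in edgeR's quasi-likelihood test (lowest adjusted p = 0.103), 1649 had an unadjusted p under 0.05, and DESeq2's likelihood ratio test called 24. On simulated data, where genes were changed only in the set of 5 tumours, 14% of those changed by a log2 size of 1 were found. Changes in the sets of 20 and 8 tumours were not simulated.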

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

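The acinar, library total, thinning and left-out shallowest-library tests were chosen after the result was seen, and the others before. A count is taken as similar within 1.5 times, and a median level within the SD of its gene. A slope or correlation is taken as similar where it stayed on the same side of the threshold, whatever its size. A sign change counts only where a value passed the threshold. Over all results and alternatives 4121 values were similar in this sense, which does not measure how far slopes or correlations moved. Of the others, 272 lost and 130 gained the threshold in the same direction, 197 counts or levels moved and 16 changed sign. Fitting epithelial and fibroblast covariates and DESeq2 size factors kept all 6 counts of higher and lower genes within 1.5 times. Of the single genes followed and called, those covariates kept 38 of 59, 35 of 41 and 20 of 25 with the G2/M score, CCND1 and the basal-minus-classical score. The fewest were kept with the acinar covariate for G2/M (26 of 59), with CCND1 from log2 TPM (8 of 41), and without the 2 farthest tumours for the basal-minus-classical score (14 of 25). The code set covariate kept 13 of 41 with CCND1, and leaving out the 2 farthest tumours 32 of 59 with G2/M. 

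Leaving out the 2 farthest tumours gave G2/M counts of 487 higher and 364 lower, and basal-minus-classical counts of 9 and 54. With the acinar covariate the G2/M counts were 376 and 390, with 650 of the 1791 genes shared. The slopes of CUZD1, ERP27, GNMT and PRSS3 were then 0.35, 0.13, 0.017 and 0.13. The basal-minus-classical fit then had 134 higher genes and 6 lists past the threshold. The CCND1 counts were 308 and 358 with the code set covariate, 246 and 109 with CCND1 from log2 TPM, and 491 lower with the library total covariate. With CCND1 from log2 TPM the slopes of AMY2B, CTRL, GATM, GCAT, GNMT, KLK1, SPINK1 and TMEM97 were -0.57, -0.16, -0.47, -0.05, -0.80, -0.24, -0.30 and -0.48, and 11 lists passed. The cause was not tested for these changes.

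Without a count filter, which tests more genes, 1322 genes were lower with CCND1, 464 higher and 523 lower with the basal-minus-classical score, and 22, 12 and 17 lists passed in the 3 fits. The strict filter gave 8 lists with CCND1, and epithelial and fibroblast covariates 6 with the basal-minus-classical score. DESeq2's Wald test gave 1552 higher genes with CCND1 and 273 lower with the basal-minus-classical score. With an estimated correlation 1, 0 and 1 lists passed. The code sets gave 56 genes without a filter, 24 with DESeq2, and 0 to 1 when each tumour of the smallest set was left out, 1 without tumour 4. The cause was not tested.

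Against the G2/M score, log2(TPM + 1) and log2(TPM + 0.1) gave r = 0.463 and 0.495 for CDK4, 0.41 and 0.384 for CDK6, 0.628 and 0.59 for epithelial genes and 0.403 and 0.418 for fibroblast genes, all past the threshold. They gave 0.606 and 0.59 for nucleotide excision repair and 0.408 and 0.376 for p53 targets, against -0.14 and -0.503 from counts. TPM was used without TMM scaling, and acinar genes took from 0.00579% to 34.9% of counts. Epithelial genes gave a partial r of 0.452 given the library total. The cause was not tested. The slope of CCND1 on the basal-minus-classical score had adjusted p-values from 0.0241 to 0.216 over its alternatives. The count filter, run without a group, asks for counts in most of the tumours, so it drops genes expressed in only some of them. It kept 12 of 22 acinar, 7 of 23 basal and 3 of 12 enterocyte genes, although the acinar list had a median level of 6.13 log2 CPM. Calls in these lists cover the kept genes alone. Whether depth also limits these lists was not tested.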

Other observations

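The orderings of the tumours, the acinar covariate and partial correlation, the 6 pairs of cell type scores, the median over all islet and adipocyte genes, the adipocyte minus fibroblast test, the list medians with covariates, the thinned libraries, the 11q13 neighbours and the genes named in this paragraph were tests and choices made after the result was seen. The islet minus fibroblast and protein-coding share tests were chosen after the relations they examine and before their own results were seen. Some hypoxia, endothelial and single subtype genes also moved with the G2/M score. Neither the hypoxia nor the endothelial list ranked apart from other genes. Of 14 hypoxia genes 3 were higher and 1 lower (5 higher and 1 lower when adjusted over the list alone), the carbonic anhydrase CA9 at 1.10 ± 0.36, the glycolytic ENO1 at 0.33 ± 0.11 and BNIP3 at -0.93 ± 0.22 (camera adjusted p = 0.104). Of 12 endothelial genes EMCN at -0.71 ± 0.23 and the clotting factor carrier VWF at -0.32 ± 0.11 were lower (0 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.154). AGR2, of the classical subtype list, rose by 0.88 ± 0.24, the macrophage gene CD68 by 0.37 ± 0.11 and the 11q13 genes CTTN and ANO1 by 0.30 ± 0.08 and 0.46 ± 0.13, while the immediate early gene JUN had a slope of -0.41 ± 0.12.

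The 3 axes shared higher genes. Of the genes higher with the G2/M score, 129 were also higher toward the basal end, against 12.2 for independent lists, and 118 were also higher with CCND1, against 57.6. CCND1 and the basal-minus-classical score shared 87 higher genes, against 12.7, and 44 lower genes, against 7.48. Genes lower with the G2/M score shared 39 with those lower with CCND1, against 42.9, and 18 with those lower toward the basal end, against 8.66. In opposite directions, G2/M and CCND1 shared 0 genes higher and lower, against 45.6, and 33 lower and higher, against 54.2. The expected values take genes as independent, which they are not. They also take the axes as unrelated, although all 3 come from the same 33 tumours. CCND1 and the basal-minus-classical score correlated with each other (r = 0.503). An excess over the expected values therefore shows no sharing beyond that of related axes.

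Chance was tested with 40 orderings of the tumours per fit. Of the 40, 1 gave as many genes as the G2/M score, the real one (1791 genes, highest other 8). This is the smallest share that 40 orderings can give. The same held for CCND1, with 1 of 40 (1708, highest other 7). For the basal-minus-classical score it was also 1 of 40 (355), but another ordering gave 226. Orderings this few do not exclude chance. The real title code sets gave 0 genes, which every ordering reaches (40 of 40), so this count says nothing about chance (highest other 46). The 3 covariates come from the same expression values as the genes, so an excess over shuffled orderings does not set these axes apart from others.

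The lower levels of some acinar and islet genes and of adipocyte genes with the G2/M score may reflect how much normal pancreas a sample held, and the acinar score fell with the G2/M score (r = -0.513, p = 0.00255, adjusted over 6 pairs p = 0.0123, rho = -0.532 with permutation p = 0.00185, r = -0.428 without the 2 farthest tumours, -0.33 in set A and -0.858 in set B). So did the islet score (r = -0.49, adjusted p = 0.0123, r = -0.358 without the 2 farthest tumours, -0.26 in set A and -0.846 in set B). The islet score rose with the acinar score (r = 0.418, adjusted p = 0.0312, r = 0.117 in set A and 0.772 in set B). Both islet relations were much weaker in set A than in set B. The adipocyte score did not pass against G2/M (r = -0.336, adjusted p = 0.0838, rho = -0.268 with permutation p = 0.132, r = -0.2 without the 2 farthest tumours, -0.133 in set A and -0.52 in set B). It did not pass against the acinar score either (r = 0.1, adjusted p = 0.584), nor did endothelial genes (r = 0.137, adjusted p = 0.538). For E2F targets the partial r given the acinar score was 0.858. The E2F and G2/M scores correlated so strongly (r = 0.865), and the acinar score so much less (r = -0.513), that a low value was not possible. That partial r therefore decides nothing about acinar content. As the whole cause, acinar content is argued against for islet and adipocyte genes. The median slope over all 20 tested members was -0.866 with the acinar score as a covariate. With the acinar covariate 4 of 9 called islet and adipocyte genes were still past the threshold, between the bounds of at most 2 and at least 6 set for that test. Their median slope went from -0.91 to -0.99 and its SE from 0.24 to 0.27, and why the other calls ended was not tested. A higher share of tumour epithelium that lowers all other cell types alike is argued against for islet genes. Islet minus fibroblast levels fell with the score (r = -0.54, permutation p = 0.00131). A higher share of tumour tissue, fibroblasts included, stays open, since fibroblast genes had a median slope of 0.17 and were not lower. With epithelial and fibroblast covariates the median slope of 16 islet genes went from -0.76 ± 0.32 to -0.61 ± 0.37 (median SE), with 0 called. For adipocyte genes a lowering of all cell types alike stays open. Adipocyte minus fibroblast levels fell too (r = -0.439, permutation p = 0.0111). With these covariates, however, the median slope of the 4 genes went from -1.05 ± 0.30 to -0.36 ± 0.31, with 1 called. No biological explanation was tested, since the design has 1 group.

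Macrophage (r = 0.626, p = 8e-05, adjusted p = 0.0018, rho = 0.581 with p = 0.00048) and T cell (r = 0.58, p = 0.00038, adjusted p = 0.00274, rho = 0.538 with p = 0.00109) genes rose with the log2 library total, in a family of 36 lists of which 18 passed. The r was 0.565 without the 2 farthest tumours, 0.709 in set A and -0.145 in set B for macrophage genes and 0.549 without the 2 farthest tumours, 0.67 in set A and 0.2 in set B for T cell genes, so the 8 tumours of set B gave no support for either. A floor on counts in shallow libraries is argued against, since after thinning every library to the total of the shallowest the lower of the 2 correlations was 0.575 and 14 lists passed. The protein-coding share of the library is argued against by the lower partial r of 0.653 given that share. RNA quality otherwise stays open, since mitochondrial (r = 0.592, p = 0.00036, adjusted p = 0.00274, rho = 0.566 with p = 0.00079) and replication histone genes (r = 0.628, p = 0.0001, adjusted p = 0.0018, rho = 0.542 with p = 0.00138) also rose with the library total. The mitochondrial list took a median of only 0.0017% of counts, so its rise says little about RNA quality. For cell cycle measures, r with the log2 library total was 0.692 for CDK4, 0.521 for RB1 and 0.441 for the E2F score. It was 0.24 for the G2/M score, 0.196 for CCND1 and -0.0417 for CDK6. What else varied with depth stays open too, and no biological explanation was tested.

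The range of CCND1 may be thought to follow copies of the 11q13 segment, but such copies would raise its neighbours too. The median slope of the 9 neighbours on CCND1 was 0.014, with 1 of 9 past the threshold, so they did not rise with it as a set. All 12 tested acinar genes had slopes above 0 on CCND1 (median 1.62), and the neighbours' median was not adjusted for tissue content. The test therefore cannot decide whether copy number was the cause. No biological explanation was tested.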
